A study of Mus musculus with 12 samples.

How the data were processed

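RNA sequencing libraries were made from total RNA of mouse peritoneal macrophages, lysed in TRIzol, with a standard Illumina protocol, per the labels' protocols. The read trimmer fastp and the mm10 build are named in the submitters' processing notes. The aligner, the counter, the strand setting and the annotation release are not given in the sources used here. Because strand use is not stated, genes that overlap on opposite strands cannot be told apart, and near-identical copies may share counts. The authors deposited 1 table of 48709 genes with total counts per gene and library, not normalized, and TPM values in the same table, per the file headers. Counts were used for every test. The deposited TPM values were used only to check the counts: for genes with at least 50 counts the ratio of count to TPM deviated by at most 0.96% from that of the gene in other libraries. Of the gene IDs 48349 (99.3%) were found in GENCODE M21, which supplied exon lengths, and 88.4% of these had the same start and end.

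Samples were grouped by genotype and hours of LPS as their titles give them, and every column was matched to a sample by its title. The treatment label names LPS for all samples, 0 h included, and the series design text speaks of mock cells. Total counts ran from 14762709 to 20778862, and 1 count was worth 0.0469 to 0.0647 CPM. No pair of replicates agreed within sampling noise: chi-square per degree of freedom was 1.93 to 2.68 for replicates 1 and 2, the closest pair in all 4 groups by this measure, and 3.04 to 27.9 for the other pairs. By Pearson correlation of log2 CPM they were the closest pair at 0 h only. At 3 h they gave 0.99126 in WT and 0.99164 in MKO, against 0.99173 and 0.99198 for replicates 2 and 3. From chi-square alone replicates 1 and 2 may be technical replicates, which would leave 2 samples per group, and for this reason they were also summed. All 12 libraries were kept.

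Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM scaling, filterByExpr on the 4 groups) in 1 model with a mean per group and all 12 libraries, and 12455 of 19195 genes with any count were tested. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no fold minimum. There were 5 comparisons: LPS in WT, LPS in MKO, genotype at 0 h, genotype at 3 h, and the interaction of genotype and LPS. SE is the fold change divided by the square root of its F statistic. CPM values use TMM-scaled library sizes. Gene lists (31, with 701 members) were fixed before the data were examined and tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated per list. Floors use 3 counts over a group, on TMM-scaled library sizes like the ratios given with a counting interval, and cover counting error only.

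Named genes followed a rule fixed at the same time. It takes Usp5, then per comparison the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM and, between 2 groups, no overlap of values, then per list the 3 members with the smallest p, and a gene named in 1 comparison may be given in the others. Genes without an official-style name were left out, and fewer were named where space asked, in the order of the rule. Results for some genes that the rule names are not reported here.

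The fit was tested on simulated data, with 200 genes changed per comparison. All genes had the same coefficient of variation (0.085), changed genes had at least 1 CPM, and libraries were independent with none that stand apart. The real data differ in these points, so the shares below hold for the simulated setting only. For LPS in WT it recovered 24% of 50 genes changed 1.25-fold, 84% at 1.5-fold, 94% at 2-fold and 100% at 4-fold. For the interaction the shares were 4%, 48%, 82% and 98%. Alternatives were DESeq2 1.42.0, RLE scaling, library size only, no filter or a filter at a mean of 5 CPM, a 2-fold minimum, a replicate block, only the groups compared, and each replicate left out in turn. Alternatives chosen after seeing the data were a fit without replicate 3 of WT 0 h and of MKO 0 h, a term for each library's slope of expression on exon length, and replicates 1 and 2 of each group summed into 1 library. The slope entered the fit minus its group mean. Its term thus takes up spread within groups and cannot remove a difference in slope between groups. A change of the pseudocount planned for normalized values was not run, because counts were tested, and the prior count of the fit was not varied.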

Results

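Gene expression was measured by RNA sequencing in mouse peritoneal macrophages, phagocytes of the abdominal cavity, from wild-type mice (WT) and from mice with a myeloid knockout of Usp5 (MKO). Usp5 encodes a deubiquitinase that takes apart unanchored polyubiquitin chains. Cells were sampled before (0 h) or 3 h after exposure to lipopolysaccharide (LPS), the bacterial cell wall component sensed by Toll-like receptor 4. The 12 libraries formed 4 groups of 3, named here WT 0 h, WT 3 h, MKO 0 h and MKO 3 h. Total counts ran from 14762709 to 20778862 per library, and 12455 genes were tested. Levels are CPM, counts scaled by library size and TMM factor, given as mean ± SD with n = 3. Fold changes are log2 values with their standard error (SE), and p-values are adjusted over all genes tested in edgeR's quasi-likelihood test. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

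The first principal component held 46.6% of the variance and parted 0 h from 3 h libraries, and the second (27.9%) parted the genotypes. Replicate 3 of WT 0 h and replicate 3 of MKO 0 h stood apart from their group mates, in opposite directions on the third component (-26.3 and 28.3). Xist and Malat1, nuclear RNA genes chosen after their values were seen, parted the same libraries: Xist was at 817, 765 and 1234 CPM in WT 0 h and 1174, 1238 and 602 in MKO 0 h, and Malat1 at 31.7, 29.9 and 164 and at 201, 121 and 26.3. Malat1 also varied in WT 3 h (148, 165 and 81.4).

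**Figure D1:**
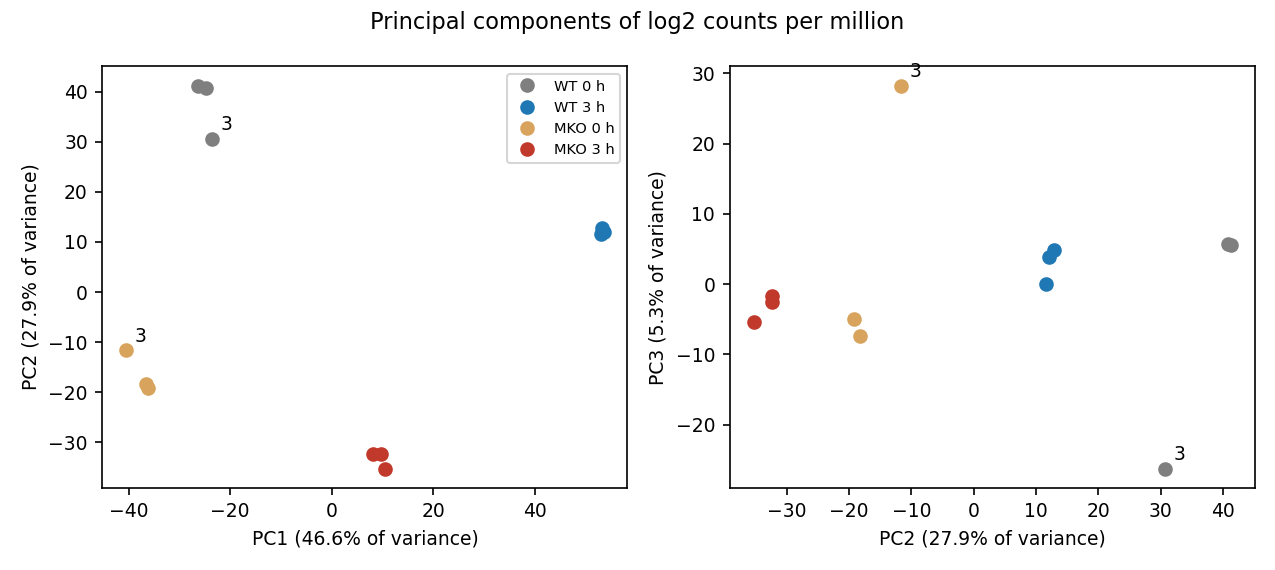
Principal components of log2 CPM, with 1 point per library coloured by group and the percentage of variance on each axis. The points marked 3 are replicate 3 of WT 0 h, at -26.3 on the third component, and replicate 3 of MKO 0 h, at 28.3.

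Usp5, the targeted gene, was low in all 6 MKO libraries. Its level was 100.6, 112 and 121 CPM in the WT 0 h libraries (mean 111 ± 10.4) and 107, 106 and 111 in WT 3 h (108 ± 2.86). It was 28.7, 29.0 and 31.4 CPM in MKO 0 h (mean 29.7) and 27.9, 28.0 and 26.9 in MKO 3 h (27.6 ± 0.621). Usp5 (ENSMUSG00000038429) is a protein-coding gene on the minus strand of chromosome 6, from 124815019 to 124829484 in mm10. The genotype difference was -1.90 (SE 0.074, adjusted p = 5.3e-10) at 0 h and -1.97 (SE 0.075, adjusted p = 1.9e-10) at 3 h, which left 26.7% and 25.5% of the WT level. LPS gave Usp5 log2 fold changes of -0.04 (adjusted p = 0.70) in WT and -0.11 (adjusted p = 0.36) in MKO, and with scaling by library size alone the change in WT was called, at -0.27.

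**Figure D2:**
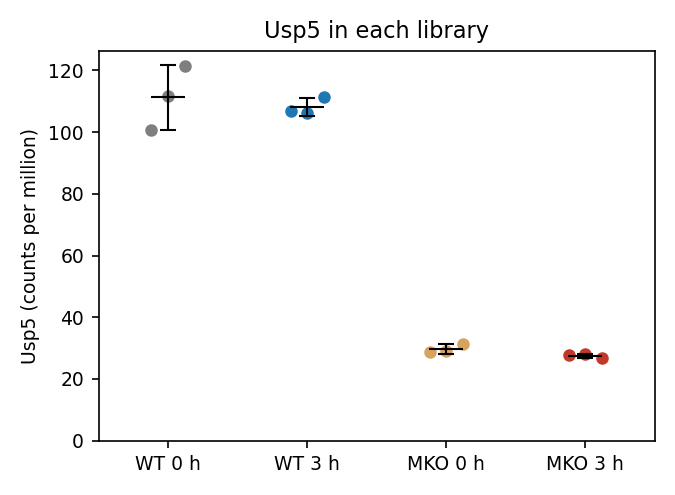
Usp5 in CPM, with 1 point per library, the group mean as a horizontal bar and the SD as error bars. WT libraries lie between 100.6 and 121 CPM and MKO libraries between 26.9 and 31.4.

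In WT macrophages LPS raised Tnf, which encodes tumour necrosis factor, from 34.3 ± 2.03 to 3214 ± 67.6 CPM (log2 fold change 6.55, SE 0.065). Il1a rose by 7.36 (SE 0.084) to 1507 ± 64.3 CPM, and Il6 by 7.41 (SE 0.22). The neutrophil-attracting chemokine genes Cxcl1 and Cxcl2 rose by 9.20 (SE 0.19) and 8.42 (SE 0.092), and Ifnb1, the interferon beta gene, by 8.83 (SE 0.26) to 49.4 ± 6.35 CPM. Ptgs2, which encodes the prostaglandin synthase cyclooxygenase 2, rose by 7.42 (SE 0.11), Tnfsf9 by 7.66 (SE 0.10), Il23a by 7.51 (SE 0.33) and Gem by 7.46 (SE 0.16). Csf3 and Tmem200b had no count in any WT 0 h library. Against a floor of 3 counts over that group they were at least 100.3-fold and 77.7-fold higher at 3 h.

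Among inflammatory cytokine genes 22 of 24 tested members rose and 0 fell (24 and 0 adjusted over the list alone), with a median log2 fold change of 3.85. All 24 immediate early genes rose, among them the transcription factor genes Maff (6.13, SE 0.11), Egr2 (5.22, SE 0.094) and Junb (2.96, SE 0.063). Of 25 genes for negative feedback on NF-kB and MAPK signalling 21 rose and 1 fell, with Nfkbiz at 5.63 (SE 0.082), Nfkbia at 3.97 (SE 0.066) and Zfp36, which encodes an RNA-destabilising protein, at 3.71 (SE 0.063). Members of the Toll-like receptor 4 pathway rose in 21 of 33 cases and fell in 5, with the co-receptor gene Cd14 at 2.19 (SE 0.068). These 4 lists were called higher with the preset correlation and with an estimated one (adjusted p = 0.00016, 0.0065, 0.00016 and 0.012 with an estimated correlation). Chemokine genes rose in 15 of 22 cases and fell in 0, and that list was not called with an estimated correlation (adjusted p = 0.13). Interferon-stimulated genes rose in 20 of 46 cases and fell in 1 (adjusted p = 0.42 with an estimated correlation), with Irf1 at 1.76 (SE 0.059) and Rsad2 at 1.31 (SE 0.052). Adjusted over the list alone, 24 immediate early, 21 feedback, 21 Toll-like receptor 4 pathway, 17 chemokine and 21 interferon-stimulated genes rose, and 0, 1, 5, 0 and 1 fell.

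Among genes that fell in WT, Igha, an immunoglobulin heavy chain gene, was at 4.91, 0.705 and 0.420 CPM in the WT 0 h libraries, and its fall of 3.95 on the log2 scale (SE 1.0) was not called without replicate 1 of that group (-2.15, adjusted p = 0.067). Zfp763 fell by 3.89 (SE 0.26), from 4.63 ± 0.195 to 0.305 ± 0.0221 CPM, Atrip fell by 3.39 (SE 0.73) and Zfp273 fell by 3.26 (SE 0.31). In all, 4042 genes changed, 2219 higher and 1823 lower, of which 642 and 420 changed at least 2-fold. With scaling by library size alone the split was 1208 higher and 5209 lower, and summing replicates 1 and 2 lowered the count to 2585. The scaling factors differ by -0.22 (log2) between these groups, and changes are relative to that shift.

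In MKO macrophages Cxcl1 rose by 8.43 (SE 0.18) to 225 ± 1.87 CPM, Cxcl2 by 7.22 (SE 0.088), Il1a by 5.85 (SE 0.082) to 339 ± 13.4 CPM and Tnf by 5.63 (SE 0.062) to 1666 ± 36.6 CPM. Id3, an inhibitor of basic helix-loop-helix transcription factors, rose by 6.15 (SE 0.14) to 130 ± 3.47 CPM, against 128 ± 7.54 CPM in WT 3 h. Csf3 had 2 counts over the MKO 0 h libraries, and its ratio of 3 h to 0 h was 88.4 with a 95% counting interval from 24.1 to 736. Inflammatory cytokine genes rose in 19 of 24 cases and fell in 0 (20 and 0 adjusted over the list alone), with a median of 2.08. Immediate early genes rose in 23 of 24 cases, and feedback genes rose in 20 of 25 and fell in 1. Those 3 lists held with an estimated correlation (adjusted p = 7.9e-05, 0.0027 and 7.9e-05). Chemokine genes rose in 13 of 22 cases and fell in 0 (15 and 0 adjusted over the list alone), and that list was not called with an estimated correlation (adjusted p = 0.079). Interferon-stimulated genes rose in 11 of 46 cases and fell in 2, and the list was not called (adjusted p = 0.062, and 0.80 with an estimated correlation). Without the pair of 0 h libraries that stand apart it was called higher (adjusted p = 7.0e-05 with the preset correlation, not run with an estimated one). Adjusted over the list alone, 24 immediate early, 20 feedback and 14 interferon-stimulated genes rose, and 0, 1 and 4 fell.

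In MKO Ier5l fell by 1.93 (SE 0.40), Cbx8 fell by 1.89 (SE 0.29), Angptl4 fell by 1.87 (SE 0.33), Zfp273 fell by 1.80 (SE 0.25) and Thbd, the thrombomodulin gene, fell by 1.73 (SE 0.16). In all, 1971 genes changed, 1214 higher and 757 lower, of which 329 and 97 changed at least 2-fold. With library size alone the split was 837 and 1758. A term for the slope of expression on exon length raised the count to 3845, and summing replicates 1 and 2 lowered it to 945, 688 higher and 257 lower. Without replicate 1, 2 or 3 of MKO 3 h 495, 494 and 428 genes were lower.

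The log2 fold changes of LPS in WT and MKO correlated across 12455 genes at Pearson r = 0.77 and Spearman rho = 0.64, where genes are not independent replicates and the comparisons share no library. Of the called genes 1071 were higher in both and 592 lower in both, where independent lists would share 216 and 111, and 5 went opposite ways. With genes of at least 5 CPM only, r was 0.90.

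**Figure D3:**
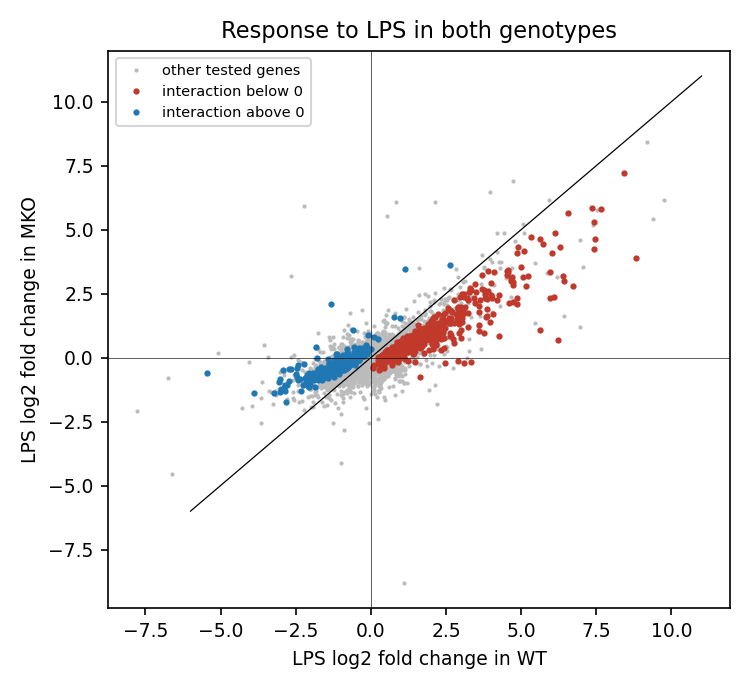
LPS log2 fold change of each tested gene in WT (x axis) and MKO (y axis), with the line of equal change. Genes with a called interaction below 0 (549) and above 0 (298) are coloured.

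Before LPS, cholesterol synthesis and cell cycle genes were lower in MKO macrophages and p53 target genes higher. Cholesterol synthesis genes were lower in 21 of 23 cases and higher in 0 (22 and 0 adjusted over the list alone), with a median of -0.68. Cyp51 was at -1.16 (SE 0.068), Idi1 at -1.11 (SE 0.069) and Msmo1 at -0.69 (SE 0.056). Target genes of the liver X receptor (LXR), a sterol-sensing transcription factor, were lower in 12 of 14 cases, with Scd2 at -1.26 (SE 0.079), Mylip at -0.74 (SE 0.059) and Nr1h3, the LXR alpha gene itself, at -0.94 (SE 0.08). Cell cycle genes were lower in 30 of 33 cases, with Rrm2 at -0.94 (SE 0.089). Of 26 p53 target genes 20 were higher and 0 lower, with Phlda3 at 2.41 (SE 0.088), Pmaip1 at 1.46 (SE 0.086) and Zmat3 at 1.34 (SE 0.096). These 4 lists held with an estimated correlation (adjusted p = 0.0070, 0.0047, 0.0047 and 0.0070).

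Markers of cell types moved as well at 0 h. Adgre1, the F4/80 macrophage marker gene, was at 3073 ± 130 CPM in WT and 1828 ± 12.6 in MKO, the summed markers of large peritoneal macrophages at 6372 ± 156 and 5141 ± 99.3, and those of T and NK cells at 260 ± 6.03 and 216 ± 9.70. Without Il7r, its most abundant gene, the T and NK cell sum was 11.5 ± 1.16 in WT and 13.1 ± 0.378 in MKO. Of 9 sums 4 were lower in every MKO library and 0 higher, but with the most abundant gene of each sum left out 0 were lower and 4 higher. In the large macrophage list Gata6, Timd4, Vsig4 and Cxcl13 stayed under 0.1 CPM in every library, 13 of 22 members were tested, and Adgre1, Itgam and Laptm5, which are not specific to that cell type, gave 97.7% of the sum. The slope of expression on exon length was -0.0664, -0.0830 and 0.0194 in the WT 0 h libraries and 0.0456, 0.0731 and -0.107 in MKO 0 h. With a term for the slope within groups, 22 cholesterol synthesis, 13 LXR target and 30 cell cycle genes were lower in MKO, and 21 p53 target genes were higher and 1 lower. That term takes up spread between group mates and does not adjust for a difference in slope between genotypes.

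Interferon-stimulated genes were lower in 37 of 46 cases and higher in 3, with Cmpk2 at -0.71 (SE 0.054) and Ifit3b at -1.12 (SE 0.09), and the list was not called with an estimated correlation (adjusted p = 0.12). Il1b was lower by -1.28 (SE 0.08), while Ccl3, which encodes a macrophage chemokine, was higher, at 138 ± 10.4 against 58.0 ± 4.99 CPM, and Egr2 was higher by 1.46 (SE 0.091). The largest differences among named genes were in Pydc3, at 120 ± 12.1 CPM in WT and 0.453 ± 0.268 in MKO (-8.08, SE 0.21), Flnc (5.15, SE 0.45), Serpinb9b (4.23, SE 0.12), Zfp365 (4.02, SE 0.47) and Ptx3 (3.90, SE 0.40). Pydc3 belongs to a family of near-identical interferon-inducible genes on chromosome 1 (173673675 to 173698392 in mm10), so reads may be shared between copies and its level is uncertain. Scd1, a fatty acid desaturase gene, was lower by -2.11 (SE 0.19), and Saa3, an acute phase gene, was at 390 ± 46.8 against 1562 ± 217 CPM in WT.

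Mitochondrially encoded genes were higher in 9 of 13 cases, proteasome subunits in 11 of 32 and heat shock genes in 9 of 20 with 1 lower (adjusted p = 0.55, 0.66 and 0.46 with an estimated correlation). Without the pair of 0 h libraries that stand apart, the adjusted p of these lists with the preset correlation was 0.094, 0.71 and 0.12. Adjusted over the list alone, 12 LXR target, 30 cell cycle and 38 interferon-stimulated genes were lower and 0, 0 and 3 higher, and 22 p53 target, 10 mitochondrially encoded, 11 proteasome and 9 heat shock genes were higher and 1, 0, 0 and 1 lower. In all, 4099 genes differed at 0 h, 2055 higher and 2044 lower in MKO, and 696 by at least 2-fold, 579 higher and 117 lower. With library size alone 3219 were higher and 1195 lower. Without both libraries 6034 genes differed, with only the groups compared in the fit 2698, and with replicates 1 and 2 summed 2156.

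At 3 h of LPS, Pydc3 was at 130 ± 8.68 CPM in WT and 0.222 ± 0.185 in MKO (-9.06, SE 0.23), a level uncertain for the reason given above. Ifnb1 stood at 49.4 ± 6.35 CPM in WT and 1.38 ± 0.198 in MKO (-5.15, SE 0.17). Il12b, which encodes a subunit shared by interleukins 12 and 23, was lower by -3.66 (SE 0.12), Il23a by -3.59 (SE 0.21), Serpinb2 by -3.28 (SE 0.11), Plagl1 by -3.27 (SE 0.24), Sele by -3.15 (SE 0.25), Il6 by -2.97 (SE 0.13), Il1a by -2.15 (SE 0.063), Il1b by -1.90 (SE 0.071) and Tnf by -0.95 (SE 0.05). Inflammatory cytokine genes were lower in 21 of 24 cases and higher in 1, with a median of -1.55. Feedback genes were lower in 19 of 25 cases, with the ubiquitin ligase gene Peli1 at -1.54 (SE 0.059) and Traf1 at -1.29 (SE 0.064). Both lists held with an estimated correlation (adjusted p = 0.0037 and 0.0051).

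Chemokine genes were lower in 16 of 22 cases and higher in 2, with Ccl4 at 312 against 1244 ± 20.8 CPM in WT (SE of the log2 difference 0.076), Ccl3 at -1.53 (SE 0.065) and Cxcl10 at -1.93 (SE 0.11). Interferon-stimulated genes were lower in 41 of 46 cases, with Rsad2 at -1.56 (SE 0.052). Neither list was called with an estimated correlation (adjusted p = 0.21 and 0.059). Cholesterol synthesis genes were lower in 23 of 23 cases, LXR target genes in 12 of 14 and cell cycle genes in 27 of 33, and all 3 held with an estimated correlation (adjusted p = 0.0062, 0.0062 and 0.0058). Mki67, a proliferation marker, was lower by -1.59 (SE 0.12). Of 26 p53 target genes 16 were higher and 6 lower (adjusted p = 0.092 with an estimated correlation), with Phlda3 at 2.64 (SE 0.089). Adjusted over the list alone, 21 cytokine, 19 feedback, 17 chemokine, 41 interferon-stimulated, 23 cholesterol synthesis, 12 LXR target and 29 cell cycle genes were lower and 1, 1, 2, 0, 0, 0 and 0 higher, and 16 p53 target genes were higher and 7 lower. Among higher genes were Flnc (5.74, SE 0.48), Zfp941 (4.30, SE 0.64), Serpinb9b (3.79, SE 0.12) and Ppm1j (3.68, SE 0.38).

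The summed markers of T and NK cells were 310.2 ± 3.27 CPM in WT 3 h and 232 ± 2.77 in MKO 3 h, and Il7r gave 95.5% of that sum over all libraries. Those of large peritoneal macrophages were 6434 ± 43.4 and 5472 ± 68.1, and 3415 ± 26.8 and 3465 ± 64.5 without Adgre1, which was lower by -0.59 (SE 0.043), or -0.34 with library size alone. Of 9 sums 7 were lower in every MKO library and 0 higher, and 3 lower and 3 higher without the most abundant gene of each. The slope of expression on exon length also parted the genotypes at 3 h, at -0.0189, -0.0238 and -0.00965 in WT and 0.0430, 0.0429 and 0.0843 in MKO. With a term for the slope within groups, 21 cytokine, 19 feedback, 16 chemokine, 42 interferon-stimulated, 23 cholesterol synthesis, 12 LXR target and 29 cell cycle genes were lower. That term cannot remove the difference in slope between genotypes, so these counts do not test its effect. In all, 5326 genes differed at 3 h, 2463 higher and 2863 lower in MKO, and 996 by at least 2-fold, 633 higher and 363 lower. With library size alone 5424 were higher and 1199 lower. Summing replicates 1 and 2 of each group lowered the count to 3434.

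**Figure D4:**
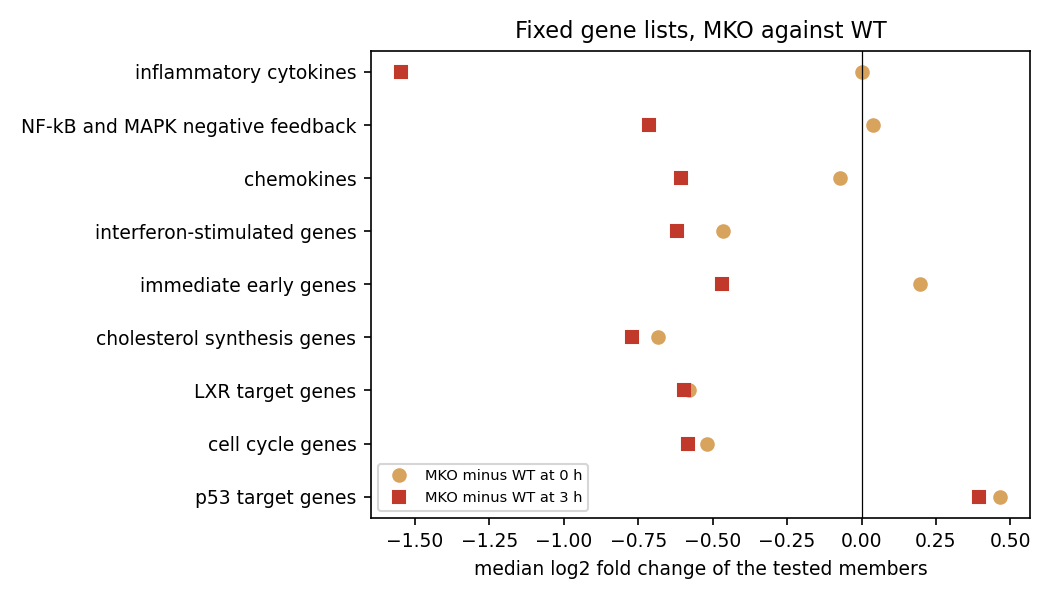
Median log2 fold change between MKO and WT of the tested members of 9 gene lists, at 0 h and 3 h. Cholesterol synthesis genes lie at -0.68 at 0 h and -0.77 at 3 h.

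The interaction asks whether LPS changed a gene by a different amount in MKO than in WT. The chemokine genes Ccl3 and Ccl4 had interactions of -2.79 (SE 0.094) and -2.52 (SE 0.11), Ptgs2 of -2.14 (SE 0.14), Egr2 of -2.02 (SE 0.12), Tnfsf9 of -1.87 (SE 0.15), Il1a of -1.51 (SE 0.11) and Tnf of -0.92 (SE 0.075). Edn1, the endothelin gene, was at -3.91 (SE 0.42). Ppp1r15a, a gene of the integrated stress response, was at -2.58 (SE 0.13), with 20.8 CPM in WT 0 h and 39.1 in MKO 0 h. Inflammatory cytokine genes had a negative interaction in 14 of 24 cases (17 adjusted over the list alone), feedback genes in 16 of 25 and immediate early genes in 14 of 24, with 0, 0 and 1 positive. These 3 lists held with an estimated correlation (adjusted p = 0.00022, 0.00039 and 0.041). Between genotypes the immediate early list was higher in MKO at 0 h and lower at 3 h with the preset correlation (adjusted p = 0.021 and 0.00015). With an estimated one it was called at neither time (0.54 and 0.21). Part of its interaction may thus lie in levels before LPS. Egr2, higher in MKO at 0 h, was lower at 3 h by -0.56, or -0.31 with library size alone. Chemokine genes were negative in 8 of 22 cases and interferon-stimulated genes in 10 of 46, and neither list held (adjusted p = 0.21 and 0.46 with an estimated correlation). Adjusted over the list alone, 19 feedback, 17 immediate early, 12 chemokine and 12 interferon-stimulated genes were negative.

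Positive interactions included Zfp763 (2.51, SE 0.35), Zfp105 (2.44, SE 0.61), Smad6 (2.35, SE 0.64) and Fbxo32, a ubiquitin ligase gene (2.22, SE 0.24), and the calls of Zfp105 and Smad6 were lost under 9 and 12 of 20 alternatives. In all, 847 genes had an interaction, 298 positive and 549 negative. Of the 2219 genes induced in WT 544 had a negative interaction, and of these 463 were lower in MKO at 3 h, 186 were higher in MKO at 0 h and 105 were both. Of the positive genes 277 were repressed in WT. With library size alone the split was 829 positive and 382 negative. The count was 2535 without the pair of 0 h libraries that stand apart and 294 with replicates 1 and 2 summed, 57 positive and 237 negative. Without replicate 1 of MKO 3 h 180 genes were positive, without replicate 2 of WT 3 h 187 and without its replicate 1 194.

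**Figure D5:**
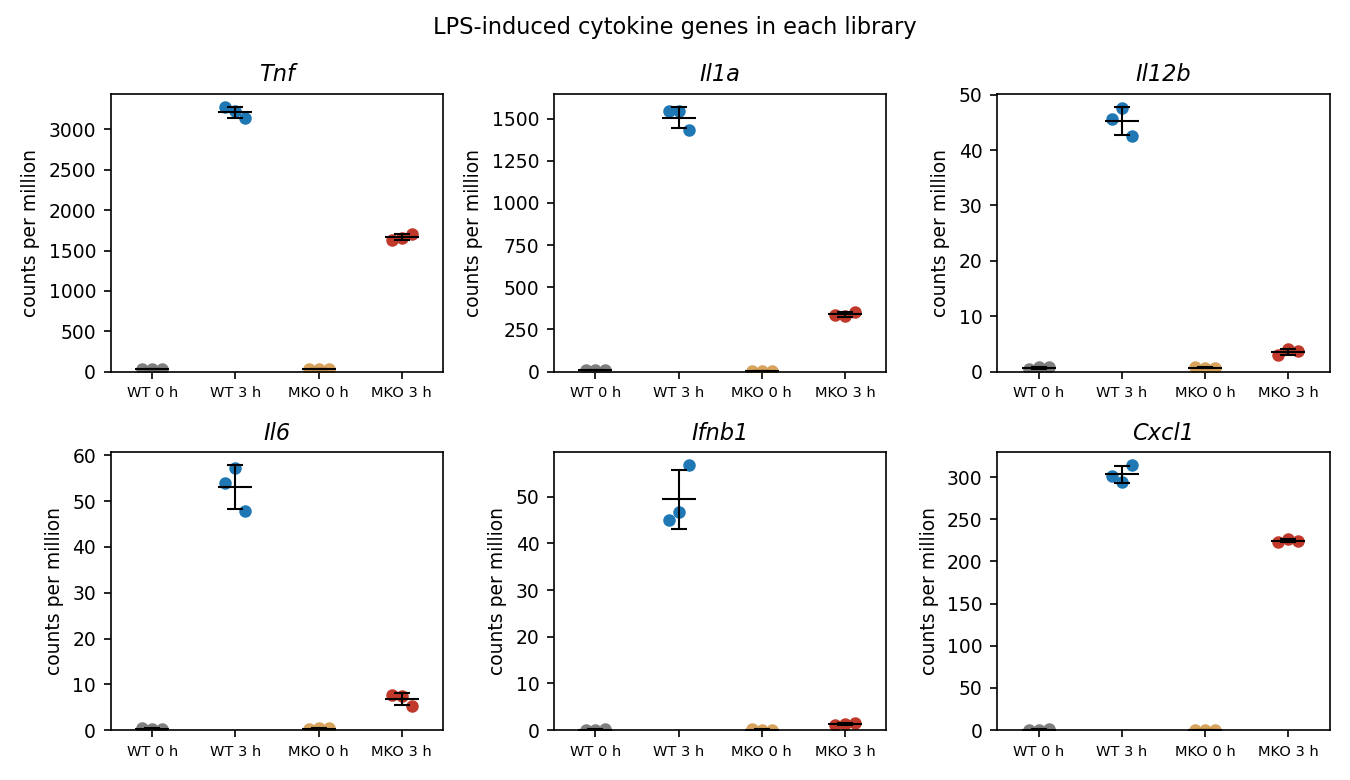
CPM of 6 LPS-induced genes, with 1 point per library, the group mean as a horizontal bar and the SD as error bars, on linear axes from 0. Tnf reaches 3214 CPM in WT and 1666 in MKO at 3 h, and Ifnb1 49.4 and 1.38.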

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

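The tests of a label swap, of leaving out the 0 h libraries that stand apart, of scaling on the cytokine list, of the macrophage marker sum and of general macrophage genes were chosen after the result was seen. The effect of LPS differed between genotypes by a test of the difference itself, for 847 genes. Among named genes with a negative interaction Csf2 was at -5.55, Ifnb1 at -4.94, Spry1 at -4.53, Edn1 at -3.91, F3 at -3.72, Il12b at -3.67, Plagl1 at -3.51, Ptx3 at -3.46 and Gfi1 at -3.43. Ptx3 was higher in MKO than in WT at 0 h (1.31 ± 0.178 against 0.0827 ± 0.0404 CPM) and at 3 h (10.4 ± 0.788 against 7.66 ± 1.09). The other genes named here had lower means in MKO at 3 h. Of these, F3 was also higher in MKO at 0 h (2.22 ± 0.0961 against 0.345 ± 0.225 CPM), so part of its interaction lies in its level before LPS. Spry1, Edn1, Gfi1 and Csf2 also had higher 0 h means in MKO (0.497, 0.497, 0.701 and 0.299 CPM). In WT 0 h they were at 0.0823, 0.221, 0.262 and 0.0396. These levels are low, but part of their interactions may lie there too. Il12b, Plagl1 and Ifnb1 were at 0.721, 0.789 and 0.0935 CPM in MKO 0 h and 0.707, 0.669 and 0.0992 in WT 0 h. Csf2 had 2 counts over the WT 0 h libraries, and its ratio of 3 h to 0 h in WT was 88.2, with a 95% counting interval from 24.1 to 734. Over the MKO 0 h libraries Csf2 had 18 counts, and its ratio of MKO to WT at 0 h was 7.69 (1.84 to 68.3). With so few counts its fitted interaction may depend on the prior count, which was not varied. The call of Ifnb1 was lost without MKO 0 h replicate 1 (-4.18, adjusted p = 0.17). Positive interactions were Zfp763 at 2.51, Zfp105 at 2.44, Smad6 at 2.35, Fbxo32 at 2.22, Zfp60 at 2.16, Mettl18 at 2.14, Zfp563 at 2.11, Zfp383 at 2.05, Zfp955b at 2.001 and Zfp472 at 1.85. Smad6 rose more in MKO (0.560 to 6.61 CPM) than in WT (0.918 to 2.04), while the others had lower means after LPS in WT. In WT 3 h Zfp105, Zfp763, Zfp563, Mettl18 and Zfp383 were at 0.199, 0.305, 0.333, 0.343 and 0.344 CPM, a few counts per library. Zfp105, Smad6, Zfp563 and Zfp383 lost their calls under 9, 12, 8 and 5 of 20 alternatives.

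Of the 2219 genes induced by LPS in WT, 544 had a negative interaction, and with library size alone the median over the 549 negative genes was -0.61, which says nothing about scaling, since those genes were chosen for their sign and the setting moved all genes alike, by 0.13. The median of the cytokine list fixed beforehand differed by -1.52 from that of all tested genes, which a factor common to all genes does not give, so scaling is argued against for that list. The 0 h libraries that stand apart are argued against too, since 97.6% of the 549 genes were still called lower without them. A macrophage share that fell with LPS in MKO is argued against as the cause of the interaction in the cytokine list. The 16 general macrophage genes had a median interaction of -0.030 against a list median of -1.54. Their median genotype difference at 3 h was -0.53, so a smaller share at both times stays open for the genotype differences. The part of such a constant share in the interaction is not addressed by these values. The 4 of 6 marker sums of other cell types that were lower in every MKO 3 h library decide nothing, since 2 were lower and 2 higher without the most abundant gene of each, nor does the large macrophage sum (interaction 0.076), which rests on 3 unspecific genes, and a change in the kind of macrophage, the genotype and any unlabelled difference between the mice remain open.

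Relabelling genotype within each time, 4 of 100 draws from 200 relabellings, the real one included, gave as many interaction genes as the 847 found, which is under 0.05, but the highest other gave 1206. The 3 others all kept the real labels at 3 h and mixed the 0 h libraries, so they hold the genotype difference at 3 h and point to a structure of the samples. The draw used 1 seed and held 7 of the 20 relabellings that keep the 3 h labels, and 4 of these 7, the real one included, gave as many genes. The share under 0.05 thus rests on draws that mixed the 3 h libraries, where the genotype difference at 3 h widens the spread within groups. A full count could give another share, so this relabelling does not decide the question. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and 1 split, the real one, gave as many genes in each comparison. LPS in WT gave 4042 against a highest other of 0, LPS in MKO 1971 against 0, genotype at 3 h 5326 against 0 and genotype at 0 h 4099 against 1689. That split set WT 0 h replicates 1 and 2 with MKO 0 h replicate 3, which follows the libraries that stand apart.

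Replicate 3 of WT 0 h and of MKO 0 h deviated from their group mates in opposite directions, with a correlation of -0.65 across 7019 genes. A trend on exon length is argued against as the whole cause: it held 21.4% and 45.6% of the variance of the deviations, and the correlation was -0.51 after its removal. A swap of both labels is argued against by Usp5, whose level in MKO 0 h 3 was 0.26 of that in WT 0 h 3, and library size by the totals, with 2 of 2 libraries within the range of the other 10. What else set them apart stays open, Xist and Malat1 (chosen after their values were seen) included, and no biological explanation was tested, since the labels give none.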

How the results depend on the processing

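The fits without both 0 h libraries, with the length slope and with replicates 1 and 2 summed were chosen after seeing the data, and the slope was taken from the same libraries, so its p-values may be too small. Counts of LPS in WT, LPS in MKO, genotype at 0 h, genotype at 3 h and the interaction were, in this order, 1062, 426, 696, 996 and 248 with a 2-fold minimum, which lowers them by construction, and 2585, 945, 2156, 3434 and 294 with replicates 1 and 2 summed, which leaves fewer libraries. Library size alone gave 6417 for LPS in WT, only the groups compared 2698 for genotype at 0 h, and the length slope 3845 for LPS in MKO and 1808 for the interaction. Without both 0 h libraries the interaction gave 2535, and the cause was not tested. Leaving out each replicate in turn gave 3340 to 4436, 1335 to 2085, 3119 to 4792, 4402 to 4498 and 603 to 1132. The correlation of both LPS responses was 0.90 with genes of at least 5 CPM, which removes low genes, 0.69 without both 0 h libraries, and 0.73 to 0.76 with each replicate left out. All other counts stayed within 1.5 times. For 548 results of named genes, 9194 alternative values held 8778 with the same call, 269 with a lost call, 146 with a gained call and 1 reversed, and replicates 1 and 2 summed lost 49.

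The replicate block gave 3710, 1616, 3703, 4936 and 672 genes. Over 18 pairs with the same number the correlation of deviations ran from -0.34 to 0.078. This gave no sign that libraries with the same number deviated alike, but it cannot exclude a pairing or a batch. Usp5 kept its direction and call between genotypes under every alternative run, and LPS in WT was called for it only with library size alone (-0.27). Without both 0 h libraries 3 lists turned direction with the preset correlation, proteasome subunits for LPS in MKO (adjusted p = 0.034) and for the interaction (0.014) and oxidative phosphorylation genes for the interaction (0.0035), and none had been called before. The correlations estimated for proteasome and oxidative phosphorylation genes in the main fit were 0.70 and 0.68, far above the preset 0.01. The fit without both libraries was not run with an estimated correlation. Csf3r, higher after LPS in WT, was at -0.046 with library size alone (adjusted p = 0.48), as the factor difference of -0.22 gives. The cause of the turned lists was not tested. Depth limits low genes: 1 count was worth up to 0.0647 CPM.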

Other observations

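The comparison of neighbouring pairs with genes changed by LPS was chosen after the result was seen. Genes of MHC class I presentation were lower in MKO in 8 of 17 cases at 0 h and 10 of 17 at 3 h, and higher in 0 (adjusted p = 0.54 and 0.55 with an estimated correlation). H2-Q7 was at -1.03 (SE 0.12) and -1.35 (SE 0.11), and H2-K1 at -0.40 (SE 0.058) and -0.43 (SE 0.058), the latter -0.18 with library size alone. Clec7a, the beta-glucan receptor gene dectin-1, was at 298 ± 8.84 CPM in WT 0 h and 710 ± 35.4 in MKO 0 h, and was higher in MKO at 3 h by 1.34 (SE 0.055); it lies within 10 Mb of Usp5. Mrc1, the mannose receptor gene, was lower by -0.51 (SE 0.078) at 3 h, or -0.26 with library size alone. Atp6v0d2, a subunit gene of the vacuolar proton pump, was higher by 0.95 (SE 0.051) and 0.90 (SE 0.051). Hmox1, which encodes the haem-degrading enzyme heme oxygenase 1, was lower by -0.88 (SE 0.057) and -0.77 (SE 0.057).

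Cdkn1a and Mdm2, p53 targets that LPS also induced, differed by 0.79 (SE 0.056) and 0.35 (SE 0.046) at 0 h, with interactions of -0.93 (SE 0.079) and -0.72 (SE 0.065), and Mdm2 was lower in MKO at 3 h by -0.38 (SE 0.045), or -0.13 with library size alone. Siglecf, a marker gene of eosinophils and of some macrophages, was at 1.69 CPM in WT 0 h and 10.8 in MKO 0 h (2.67, SE 0.17), while Ccr3, another eosinophil marker gene, was lower by -0.96 (SE 0.10). Mmp12, a macrophage elastase gene chosen after its values were seen, was at 828 ± 13.8 CPM in WT 0 h and 3393 ± 38.8 in MKO 0 h.

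Large genotype differences of the same sign at both times covered 416 genes besides Usp5, 345 higher and 71 lower in MKO. A passenger region around Usp5 remains open, with 9 of 155 tested genes within 10 Mb in the set, Clec7a among them, a share 1.75 times that elsewhere (Fisher's exact test, two-sided, p = 0.11). Strain segments elsewhere cannot be told apart from shared regulation of neighbours: 32 neighbouring pairs were both in the set, against at most 25 in 1000 random sets, but the 416 genes that LPS changed most in both genotypes gave 48. Pydc3, nearly absent in MKO at both times, is in the set. The nearby Pydc4 and Ifi204, chosen after their values were seen, were lower by -0.76 and -0.58 at 0 h. Gm16867, chosen likewise and outside the naming rule, had no count in WT 0 h and was at 7.81 ± 0.700 CPM in MKO 0 h. No single locus was tested for a strain segment. Exon length is argued against as a trait of the pooled set, with a difference of medians of -0.076 (log2). Higher and lower genes were not compared separately, so length trends of opposite sign in them are not excluded. The genotype itself stays open as an explanation.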
